A study of Mus musculus with 10 samples.

How the data were processed

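Expression was measured in 10 mouse samples on 1-colour Affymetrix mouse exon arrays from total RNA extracted with Trizol and labelled with biotin. The text of the series names 2 versions of the array. Tumour samples were dissected brain-derived tissue, and cultures were pelleted neurospheres. The deposited values are log2 expression summaries, 1 per transcript cluster and sample, that per the submitters' processing notes were made with Partek and RMA on genome build mm8. RMA corrects background, normalizes quantiles between arrays and summarizes probes; the versions of these tools and the way probe sets were combined are not given in the sources used here. The 10 arrays do not share one distribution, so the values were checked and used as deposited, with no further normalization, filter or pseudocount. As they were already on a log2 scale, no log transformation was applied, and all 10 per-sample columns were used.

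Samples were grouped by their labels as PNET (n = 3), AdCre-induced oligo-astrocytoma (n = 1), grafted oligo-astrocytoma (n = 3), AdCre sphere (n = 2) and AdGFP sphere (n = 1). Both kinds of oligo-astrocytoma formed 1 group in the 3 main comparisons, since 3 of 4 came from grafts and all PNET from injection, which nearly ties tumour type to derivation. Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 to all 10 samples in 4 groups, or in 5 for the comparison within oligo-astrocytomas. Tests were two-sided, and Benjamini-Hochberg adjustment ran over all 23238 transcript clusters, with a threshold of 0.05. Single samples were assumed to vary like the other groups. A probe annotation table names 1 gene for 14939 transcript clusters, several for 989 and none for 7310; for the 131 genes with more than 1 transcript cluster, the one with the highest mean was used.

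The models, groups, named-gene rule, gene lists and alternatives, except 4 that were added later, were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls of each main comparison, among genes past the threshold whose groups did not overlap, passing over predicted genes without a standard name. The other comparisons took 5 in each direction, or the 5 smallest unadjusted p where fewer passed. Up to 4 members per direction of each gene list, or the 2 largest where none passed, and the targeted genes were added. The 31 gene lists hold 738 genes, of which 610 were measured, and 29 genes stand in more than 1 list. The lists cover targeted genes, p53 targets, E2F and S-phase, mitosis, Ink4a-Arf and senescence, neural stem and progenitor, neuronal lineage progenitor, mature neuron, astrocyte, oligodendrocyte precursor, mature oligodendrocyte, microglia and macrophage, lymphocyte, endothelial, pericyte and smooth muscle, fibroblast and matrix, choroid plexus and ependyma, red blood cell, photoreceptor and pineal, hindbrain and cerebellar, forebrain patterning, Sonic hedgehog, Wnt, Notch, receptor tyrosine kinase, interferon and MHC class I, hypoxia, cholesterol synthesis, immediate early and stress, mesenchymal glioma, and MYC and telomerase genes. The 30 lists with at least 5 measured members were tested against all other genes with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists within a comparison. Beside camera, limma's fry was run, which tests a list on its own and not against other genes. Alternatives were quantile normalization between the arrays, centring on the array median, filters on dim transcript clusters, trended and robust or no variance moderation, array weights, fits of the compared groups only, other sphere or oligo-astrocytoma groupings, a block for the sample number, and leaving out each replicate.

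For the comparison of both tumour types with the same spheres, 100 simulations of unchanged groups gave the overlap and correlation that shared controls produce. Gene order was taken from the GRCm38.p6 assembly, which differs from the build of the arrays, so no positions are given. Running medians of 25 genes with a mean of at least 5 were taken along each of 20 chromosomes, as the difference of a sample from the median of the others of its type, centred on 0 per sample. Runs had a running median beyond 0.45 over at least 10 genes, and chromosomes were called shifted where their median lay beyond 0.15. These thresholds, a rule that holds the running median constant at chromosome ends, and the retina and pineal marker lists were set after values had been seen, and 100 shuffles of gene order gave the chance level.

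The models were tested on simulated data with the same groups, in which 67 genes were changed 2-fold, 67 4-fold and 66 8-fold. Between PNET and oligo-astrocytoma 41.8%, 89.6% and 98.5% were recovered, and between AdCre and AdGFP spheres 1.49%, 67.2% and 95.5%, with 4 to 7 false calls among 23038 unchanged transcript clusters over the 5 comparisons. The simulated noise of a transcript cluster had the same spread in every group. These counts therefore do not test the assumption that single samples vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Transcript clusters without a single gene name were tested but not named. DNA was not analysed here, and human samples named in the title of the series were not used here.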

Results

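RNA from 10 mouse samples was measured on Affymetrix mouse exon arrays, 1 colour per array. All samples came from mice in which both copies of Trp53 (p53) and Rb1, a pair of tumour suppressor genes, are flanked by loxP sites, so that adenovirus carrying Cre recombinase (AdCre) deletes them. The tumour samples were 3 primitive neuroectodermal tumours (PNET) that arose after AdCre was injected into the brain ventricles, 1 oligo-astrocytoma that arose after the same injection (replicate 44), and 3 oligo-astrocytomas grown from grafted AdCre-transduced neurospheres (replicates 4, 5 and 6). The cultures were neurospheres of the subventricular zone at passage 3, of which 2 had received AdCre and 1 had received a control adenovirus with green fluorescent protein (AdGFP). Values are log2 expression for 23238 transcript clusters, of which 14807 stand for a named gene, and array medians ranged from 5.87 to 6.06. Across transcript clusters, correlations were 0.957 to 0.974 between PNET, 0.951 to 0.967 between oligo-astrocytomas and 0.971 to 0.975 between spheres. They were 0.902 to 0.919 between PNET and oligo-astrocytomas, 0.894 to 0.918 between oligo-astrocytomas and spheres, and 0.855 to 0.888 between PNET and spheres, and the first principal component held 47.2% of the variance. Changes below are log2 differences ± SE, and the number of arrays limits their precision. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples.

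Of the targeted genes, Rb1, which restrains entry into the DNA synthesis phase, read 8.48 in the AdGFP sphere and 6.65 and 6.34 in the AdCre spheres. It read 7.48, 7.48 and 7.64 in the PNET, 6.97 in the AdCre-induced oligo-astrocytoma and 6.36, 7.24 and 6.63 in the grafted oligo-astrocytomas. The Rb1 value covers a whole transcript cluster, whose probes may lie outside the deleted part. No transcript cluster was annotated to Trp53.

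The first comparison, PNET (n = 3) against oligo-astrocytoma (n = 4), asks how the embryonal tumour differs from the glioma. Of the measured photoreceptor and pineal genes, 15 of 25 were higher in PNET, and of the oligodendrocyte precursor genes 18 of 23 were lower. Both lists were called as groups at the preset correlation but not with an estimated one (adjusted p = 0.0837 and 0.0772). Otx2, a homeobox regulator of early forebrain, retina and pineal gland, was 6.74 ± 0.36 higher in PNET (adjusted p = 9.82e-06), at 11.54 ± 0.29 (SD, n = 3) against 4.80 ± 0.21 (SD, n = 4). Pdgfra, the platelet-derived growth factor receptor of oligodendrocyte precursors, was lower by a log2 change of -6.39 ± 0.26 (adjusted p = 2.693e-06), at 4.62 ± 0.08 in PNET against 11.01 ± 0.19 in oligo-astrocytoma. The neural stem cell factor Sox2 changed by -5.60 ± 0.24 (adjusted p = 3.151e-06), from 10.05 in oligo-astrocytoma to 4.45 in PNET. Of the 23238 transcript clusters, 2960 changed, 1286 higher and 1674 lower in PNET, or 1045 and 1371 named genes. The larger side depends on the scaling, with 1671 higher and 1549 lower after quantile normalization (1347 and 1264 named genes), and 1538 and 1498 with each array centred on its median.

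Further rises in PNET included Crx, the photoreceptor and pineal transcription factor, at 6.33 ± 0.37, and Tph1, the first enzyme of serotonin and melatonin synthesis, at 6.65 ± 0.39. The neurogenic factors Neurod1 and Neurod4 rose by 6.54 ± 0.33 and 5.96 ± 0.58. Their list, the neuronal lineage progenitor genes, had 3 rises and 6 falls in 29 members and a median of -0.14, and was not called (camera adjusted p = 0.462). Rbp3, the retinoid carrier of the photoreceptor matrix, rose by 5.75 ± 0.20, Impg2 of the same matrix by 6.32 ± 0.26, and the cone genes Pde6c (a phosphodiesterase) and Gnat2 (a transducin subunit) by 6.32 ± 0.35 and 5.62 ± 0.24. Chrna3, a nicotinic acetylcholine receptor subunit, rose by 5.67 ± 0.20, and Tc2n and Tmem215 rose by 6.84 ± 0.63 and 6.12 ± 0.27. Among the falls, the oligodendrocyte lineage regulator Sox6 changed by -5.52 ± 0.23, the proteoglycan Vcan by -5.40 ± 0.66, the myelin-related Bcas1 by -5.17 ± 0.42 and the glial connexin Gjc3 by -5.61 ± 0.74. Vxn (-6.08 ± 0.38), the adhesion receptor Adgrl3 (-5.37 ± 0.20), Brinp3 (-5.34 ± 0.27), the adhesion molecule Ncam2 (-5.29 ± 0.28), the precursor receptor Gpr17 (-5.15 ± 0.74) and Luzp2 (-5.13 ± 0.76) completed the largest falls. These 24 genes were taken from those whose groups did not overlap, and all 24 passed again when any single sample was left out. For 15 of them, among them Tc2n, Tmem215, Pde6c, Gnat2 and Tph1 (2.67, 3.12, 2.87, 3.61 and 3.61 in oligo-astrocytoma), the mean of the dimmer group lay below the lower quartile of its arrays, where background limits the size of a change. Gpr17 and Luzp2 did not pass with the AdCre-induced tumour alone on the oligo-astrocytoma side (adjusted p = 0.0669 and 0.0637).

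**Figure D1:**
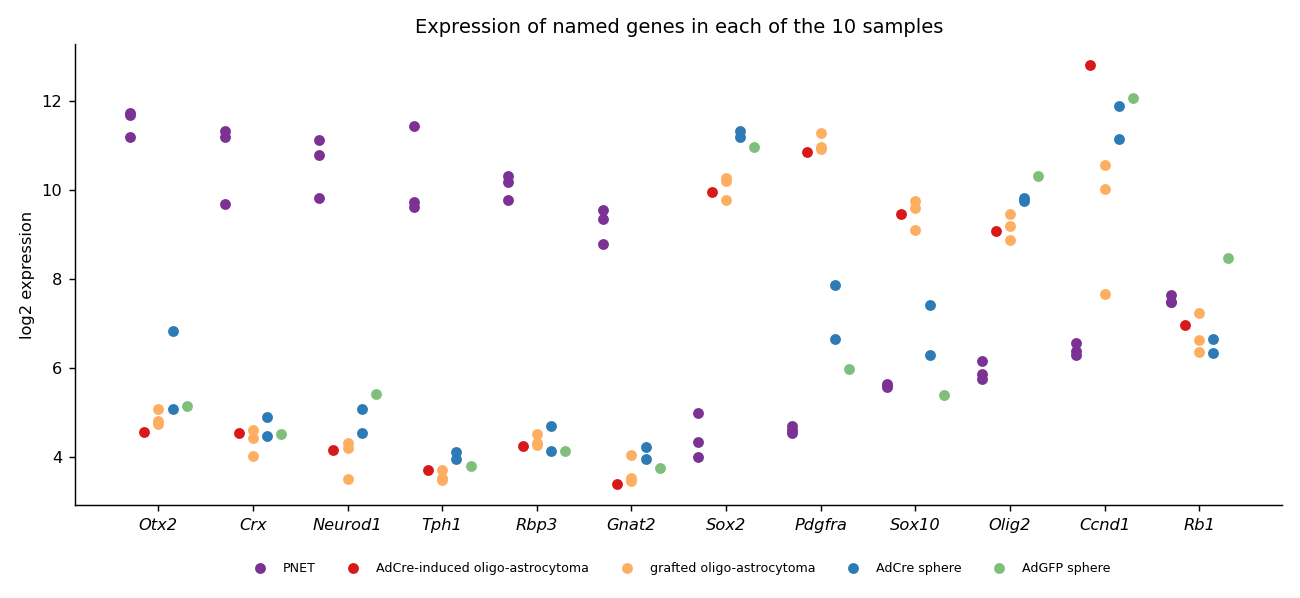
Log2 expression (vertical axis) of 12 named genes in each of the 10 samples, 1 point per sample, coloured by group. Otx2 lies above 11 in the 3 PNET and Pdgfra above 10 in the 4 oligo-astrocytomas, while Rb1 is highest in the AdGFP sphere at 8.48.

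Of 25 measured photoreceptor and pineal genes, 15 rose in PNET and 0 fell (18 and 0 adjusted over the list alone), with a median change of 1.65. The list was higher than other genes (camera adjusted p = 5.738e-13; adjusted p = 0.0837 with an estimated correlation). E2F and S-phase genes, which copy DNA under the control of the retinoblastoma pathway, had 17 of 36 members higher and 0 lower (26 and 0 adjusted over the list alone), with a median of 0.73. Slbp, which processes histone messengers, rose by 2.81 ± 0.31, the transcription factor E2f1 by 1.85 ± 0.24 and the replication licensing factor Cdt1 by 1.76 ± 0.20. That list's adjusted p was 2.044e-12, and adjusted p = 0.188 with an estimated correlation. Its number of rises was 5 without PNET replicate 3, 11 without PNET replicate 1 or grafted replicate 4, and 9 without grafted replicate 6. Mitosis genes had 3 of 34 members higher (0 adjusted over the list alone) and a median of 0.47, with adjusted p = 7.774e-05 and adjusted p = 0.628 with an estimated correlation. The 3 were Spc25, Kif23 and Anln, which passed in none of the fits without PNET replicate 1, PNET replicate 2, PNET replicate 3 or grafted replicate 4, where 0 mitosis genes rose. Without the AdCre-induced tumour or without grafted replicate 6, 1 rose, and without grafted replicate 5, 7 rose.

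Mature neuron genes rose for 10 of 24 members with 0 falls, the same numbers adjusted over the list alone, and a median of 0.56. Snap25, of the synaptic vesicle fusion machinery, rose by 4.06 ± 0.56, the vesicle protein Syp by 3.85 ± 0.33 and the vesicular glutamate transporter Slc17a7 by 3.45 ± 0.48. The list's adjusted p was 0.000992 (adjusted p = 0.0837 with an estimated correlation), and 6 members rose without PNET replicate 2 or PNET replicate 3. In the choroid plexus and ependyma list, 4 of 16 rose (6 adjusted over the list alone) and 0 fell, among them Otx2, Calml4 by 4.05 ± 0.55 and the folate receptor Folr1 by 1.66 ± 0.23. Its adjusted p was 0.00206, and adjusted p = 0.0837 with an estimated correlation. Immediate early and stress genes rose for 5 of 24 members (10 adjusted over the list alone), with a median of 0.63, adjusted p = 0.000207 and adjusted p = 0.174 with an estimated correlation. Of these, the stress factor Atf3 rose by 1.80, and 2 members rose without PNET replicate 2, PNET replicate 3 or grafted replicate 6, and 3 without PNET replicate 1, grafted replicate 4 or grafted replicate 5.

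Oligodendrocyte precursor genes fell in PNET for 18 of 23 members and rose for 0 (22 and 0 adjusted over the list alone), with a median of -2.90. The lineage factors Sox10, Olig2 and Olig1 changed by -3.86, -3.23 and -3.19, and the proteoglycan Cspg4 by -1.85 ± 0.35. The list's adjusted p was 2.314e-16, and adjusted p = 0.0772 with an estimated correlation. Astrocyte genes fell for 14 of 25 and rose for 1 (20 and 1 adjusted over the list alone), with a median of -1.69. Gpr37l1 changed by -4.32 ± 0.45, the calcium-binding S100b by -3.75 ± 0.37, the glycolytic enzyme Aldoc by -3.25 ± 0.40 and the filament protein Gfap by -3.64 ± 0.63. The 1 rise was Atp1b2, a sodium pump subunit, by 0.97, which did not pass without PNET replicate 3 (adjusted p = 0.148). Camera gave the astrocyte list adjusted p = 1.21e-09, and adjusted p = 0.174 with an estimated correlation.

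Mature oligodendrocyte genes fell for 10 of 22 members and rose for 0 (12 and 0 adjusted over the list alone), with a median of -2.09, or -1.35 without grafted replicate 4. Ugt8a, the enzyme that makes the myelin lipid galactosylceramide, changed by -4.69 ± 0.63 and myelin basic protein, Mbp, by -2.61. The list's adjusted p was 4.755e-06, and adjusted p = 0.594 with an estimated correlation. Receptor tyrosine kinase and ligand genes fell for 9 of 25 and rose for 1, also adjusted over the list alone, with a median of -0.60. Ntrk2, the receptor of brain-derived neurotrophic factor, changed by -3.88 ± 0.63, and Kit and Erbb3 by -3.70 and -3.32. The 1 rise, Igf1r by 0.90, did not pass without PNET replicate 3 (adjusted p = 0.167). The list's adjusted p was 0.000208, and adjusted p = 0.0837 with an estimated correlation. Microglia and macrophage genes had 1 of 26 members lower (0 adjusted over the list alone), Cx3cr1 by -1.13, and a median of -0.54. This call (adjusted p = 0.00593; adjusted p = 0.727 with an estimated correlation) was lost without PNET replicate 1 (adjusted p = 0.113), without the AdCre-induced tumour (0.107) or without the dimmer transcript clusters (0.269), and Cx3cr1 did not pass without PNET replicate 1 (0.136).

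Among lists that were not called, p53 target genes had 3 rises and 3 falls in 33 members (5 and 3 adjusted over the list alone). The cell cycle inhibitor Cdkn1a was 2.98 ± 0.43 higher in PNET (adjusted p = 0.00220), and Dglucy rose by 1.34 ± 0.18. Neural stem and progenitor genes had 2 rises and 7 falls in 24, among them Hes1 by 2.07 ± 0.26, Notch1 by -2.45 ± 0.34 and Fabp7 by -2.14 ± 0.30. MYC and telomerase genes had 1 rise and 2 falls in 15, and Myc changed by -1.99 ± 0.26. Sonic hedgehog response genes had 1 rise, the co-receptor Cdon by 2.29 ± 0.21, and 4 falls in 11. Of those falls, Ccnd1 (-3.86) did not pass without PNET replicate 3 (adjusted p = 0.0853), and 1 gene fell without PNET replicate 2 or PNET replicate 3 and 2 without PNET replicate 1. The 20 interferon and MHC class I genes had 0 changes in limma (list adjusted p = 0.585). Without the AdCre-induced tumour the median of that list was 0.91, with adjusted p = 0.000323 and adjusted p = 0.638 with an estimated correlation. The mean of the list was 7.51 and 7.36 in PNET replicates 2 and 3 but 5.90 in PNET replicate 1, among the grafts at 5.69 to 6.41. Against the AdCre-induced tumour alone the median was -2.02 (adjusted p = 1.704e-07; adjusted p = 0.541 with an estimated correlation).

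**Figure D2:**
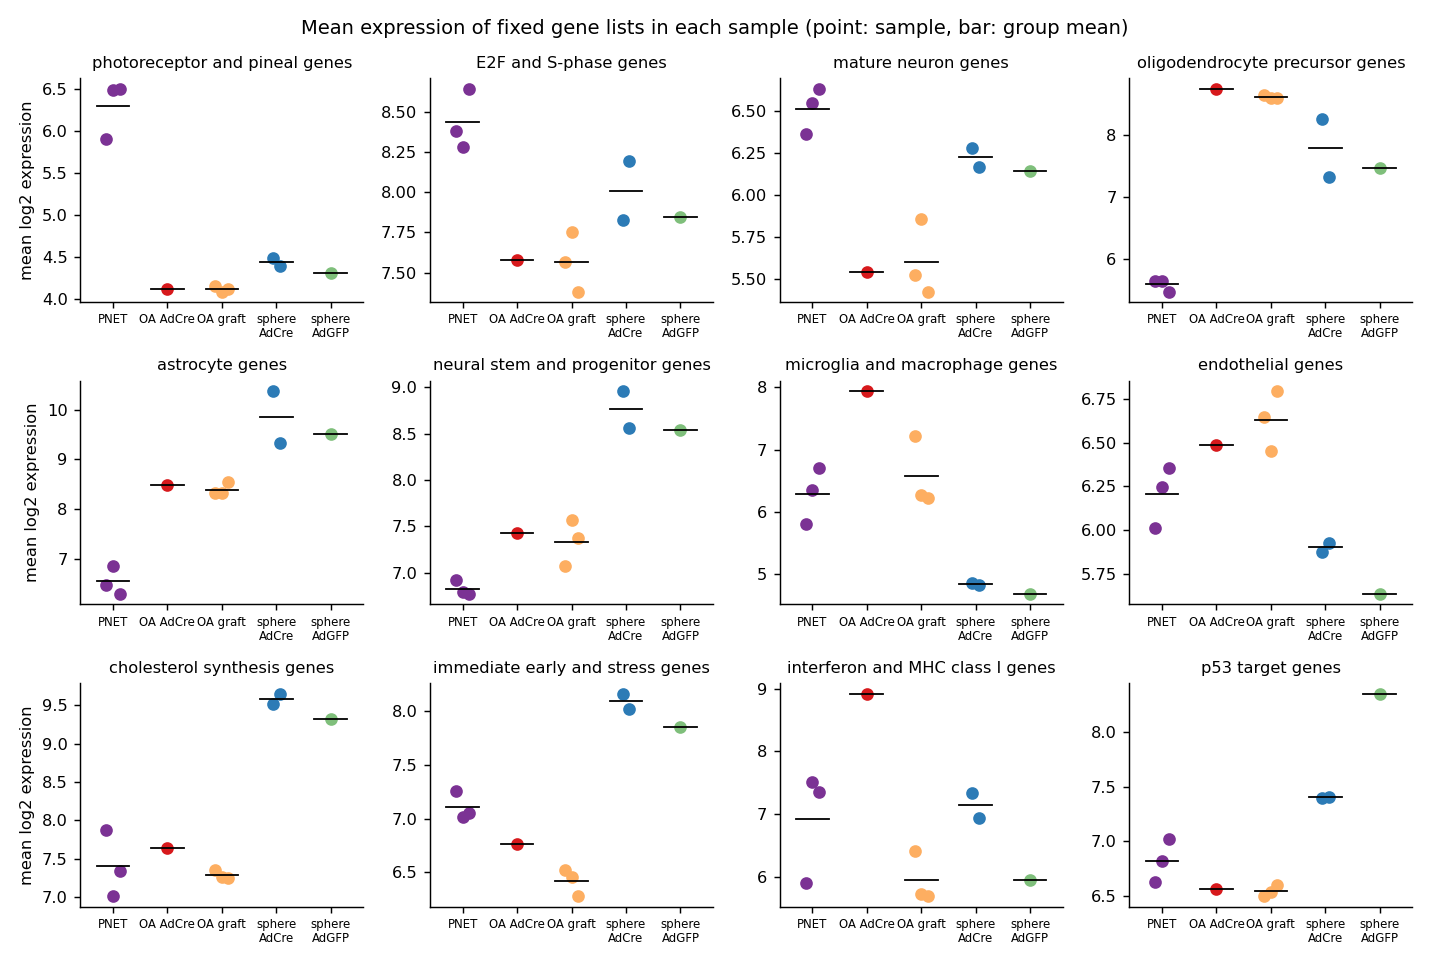
Mean log2 expression of the measured members of 12 gene lists (vertical axes) in each sample, 1 point per sample with a bar at each group mean. Photoreceptor and pineal genes average at least 5.90 in the PNET and 4.08 to 4.15 in the oligo-astrocytomas, and the interferon list is highest, at 8.92, in the AdCre-induced oligo-astrocytoma.

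The test was limma over all transcript clusters, 5920 passed at an unadjusted p under 0.05, and 23.4% of transcript clusters had groups that did not overlap, where chance gives 5.71%. The count was 1772 without PNET replicate 3 and 1182 with the AdCre-induced tumour alone, the only oligo-astrocytoma made the same way as the PNET. In that setting Cdkn1a, Gfap, Kit, Erbb3 and Atf3 did not pass (adjusted p = 0.0552, 0.079, 0.104, 0.0887 and 0.261).

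The second comparison, oligo-astrocytoma (n = 4) against AdCre spheres (n = 2), sets the glioma beside cultured subventricular zone cells that received AdCre, and addresses how tumour and stem cell cultures differ. At the preset correlation, camera called microglia and macrophage genes and endothelial genes higher in the tumours, and the cholesterol synthesis, hypoxia, and neural stem and progenitor genes higher in the spheres. With an estimated correlation it called 0 lists in this comparison, and these 5 had adjusted p = 0.242, 0.242, 0.266, 0.439 and 0.255. Ctss, a lysosomal protease of microglia and macrophages, was 5.81 ± 0.77 higher in the tumours (adjusted p = 0.000983), at 9.62 ± 1.39 (SD, n = 4) against 3.81 ± 0.15 (SD, n = 2). Pdgfra was 3.74 ± 0.30 higher (adjusted p = 0.000222), at 11.01 against 7.26. Adm, the hypoxia-induced vascular peptide adrenomedullin, changed by -5.54 ± 0.30 (adjusted p = 7.217e-05), from 10.21 in spheres to 4.67 in tumours, and Egfr, the epidermal growth factor receptor, by -3.82 ± 0.35 (adjusted p = 0.000344). In all, 7632 transcript clusters changed, 2341 higher and 5291 lower in the tumours, or 472 and 4189 named genes.

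The median change over named genes was -0.35 as deposited and -0.21 after quantile normalization, so medians of lists are also given here relative to all named genes. Other large rises were C1qb, a complement subunit made by microglia, by 4.56 ± 0.58, the myeloid genes Ms4a6c and Laptm5 by 3.96 ± 0.58 and 3.72 ± 0.49, the matrix proteoglycan Bgn by 3.94 ± 0.36 and the glial receptor Erbb3 by 3.56 ± 0.72. Large falls were Aldh1l1, a folate enzyme of astrocytes, by a log2 change of -5.07 ± 0.40, Nrn1 (-5.49 ± 0.97), the growth factor binder Igfbp2 (-4.30 ± 0.51), Fam181b (-4.03 ± 0.34), carbonic anhydrase Car2 (-3.97 ± 0.75), Kcnip1 (-3.92 ± 0.31), Pipox (-3.83 ± 0.41) and the lipase Liph (-3.80 ± 0.39). These genes passed without any single sample. Of the 24 genes with the largest changes, 6 had a dimmer group below the lower quartile of its arrays, among them Liph (2.68 in tumours) and Ms4a6c (2.88 in spheres), where background limits the size. Of the same 24, 7 did not pass without a sample, namely Apod (5.10 ± 1.20; adjusted p = 0.0664), Dcn (4.25 ± 1.29; 0.144), Car3 (-4.43 ± 1.06; 0.101) and Scd1 (-3.89 ± 0.82; 0.0505) without AdCre sphere replicate 1. Without AdCre sphere replicate 2 the same held for Gjc3 (4.29 ± 0.84; adjusted p = 0.0514), H2-Aa (3.78 ± 1.18; 0.154) and Cd74 (3.72 ± 0.99; 0.0960).

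Microglia and macrophage genes rose for 17 of 26 members and fell for 0 (18 and 0 adjusted over the list alone), with a median of 1.84, or 2.19 relative to all named genes. Its adjusted p was 3.283e-20, and adjusted p = 0.242 with an estimated correlation. Without AdCre sphere replicate 1, 7 microglia genes rose, and without AdCre sphere replicate 2, 8. Endothelial genes rose for 13 of 24 and fell for 3 (14 and 3 adjusted over the list alone), among them the surface protein Cd34 by 2.57 ± 0.27, Emcn by 2.48 ± 0.38 and the junction cadherin Cdh5 by 2.20 ± 0.31. The falls included Slc2a1, a glucose transporter, at -2.78 ± 0.38 and Bsg at -1.58 ± 0.21. Relative to all named genes the endothelial median was 1.27 (adjusted p = 2.789e-10; adjusted p = 0.242 with an estimated correlation), and 5 or 6 endothelial genes rose without AdCre sphere replicate 1 or 2. Pericyte and smooth muscle genes rose for 4 of 16 and fell for 2, also adjusted over the list alone, with a relative median of 0.69, adjusted p = 7.262e-05 and adjusted p = 0.242 with an estimated correlation, and 0 rose without AdCre sphere replicate 1 or 2.

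Fibroblast and matrix genes had 2 rises and 2 falls in 27 (1 and 2 adjusted over the list alone), with a relative median of 1.17. Bgn was among the rises, and the protease inhibitor Timp1 (-3.32 ± 0.50) and Fbln2 (-3.33 ± 0.58) were the falls. This list's adjusted p was 9.052e-07, and adjusted p = 0.255 with an estimated correlation. Oligodendrocyte precursor genes had 6 rises and 4 falls in 23 (8 and 4 adjusted over the list alone), and a relative median of 0.92. Pdgfra, Sox10 by 2.62 and Bcas1 by 3.14 ± 0.48 rose, while Epn2 changed by -1.36 ± 0.25. Olig1 (-1.04) and Olig2 (-0.63) did not pass without AdCre sphere replicate 1 (adjusted p = 0.109 and 0.175), and Olig2 did not pass after quantile normalization (adjusted p = 0.671). That list's adjusted p was 7.341e-06, and adjusted p = 0.242 with an estimated correlation. Its number of rises was 3 without AdCre sphere replicate 2, with a median of 0.09 in place of 0.56, and its number of falls was 1 without either AdCre sphere and 2 without grafted replicate 5. Mature oligodendrocyte genes rose for 7 of 22 and fell for 0, also adjusted over the list alone, with a relative median of 1.53. Enpp6, of newly formed oligodendrocytes, rose by 3.24 ± 0.65 and the myelin tight junction gene Cldn11 by 2.67 ± 0.42. Camera gave adjusted p = 1.002e-08, and adjusted p = 0.343 with an estimated correlation, and 4 and 2 genes rose without AdCre sphere replicate 1 and 2. The mean of the mature oligodendrocyte genes was 8.90 in grafted replicate 4 and 6.76 to 7.56 in the other oligo-astrocytomas, and without grafted replicate 4 their median was 0.76 in place of 1.18, with 6 rises and 1 fall.

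Cholesterol synthesis genes fell for 17 of 18 members (18 adjusted over the list alone), with a median of -2.18, or -1.82 relative to all named genes. Hmgcs1, which makes the precursor of mevalonate, changed by -3.02 ± 0.33, the mevalonate pathway enzyme Mvd by -2.84 ± 0.27, the sterol sensor partner Insig1 by -2.80 ± 0.23 and the sterol carrier Stard4 by -3.44 ± 0.29. The list's adjusted p was 1.002e-08, and adjusted p = 0.266 with an estimated correlation. Immediate early and stress genes fell for 21 of 24, also adjusted over the list alone, with a relative median of -1.12, and Ier3 and Ier2 changed by -2.72 ± 0.53 and -2.46 ± 0.25. Its adjusted p was 6.516e-06, and adjusted p = 0.242 with an estimated correlation, and 10 members fell without AdCre sphere replicate 1. Hypoxia genes fell for 15 of 22 (16 adjusted over the list alone), with a relative median of -1.29. Adm led this list, followed by the stress regulator Ddit4 at -3.17 ± 0.35 and the protein-folding oxidase Ero1a at -2.87 ± 0.45. Camera gave adjusted p = 0.000397, and adjusted p = 0.439 with an estimated correlation, and 9 fell without AdCre sphere replicate 2. Neural stem and progenitor genes fell for 14 of 24 (15 adjusted over the list alone), with a relative median of -0.90. Besides Egfr these included the forebrain factors Emx2 (-3.42 ± 0.25) and Lhx2 (-2.44 ± 0.30) and the stem cell receptor Nr2e1 (-2.35 ± 0.37). Its adjusted p was 0.00116, and adjusted p = 0.255 with an estimated correlation, and 8 fell without AdCre sphere replicate 1.

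Of the 14807 named genes, 4189 fell in oligo-astrocytoma. In lists that were not called, astrocyte genes fell for 13 of 25 and rose for 1 (list adjusted p = 0.0615). Chrdl1 changed by -3.62 ± 0.40, the fatty acid enzyme Acsbg1 by -3.27 ± 0.43 and the growth factor receptor Fgfr3 by -2.63 ± 0.22, and 8 fell without AdCre sphere replicate 1. p53 target genes fell for 14 of 33, among them Ephx1 (-3.66 ± 0.46) and Rps27l (-2.42 ± 0.23), and 9 fell without AdCre sphere replicate 1. E2F and S-phase genes fell for 9 of 36, Slbp by a log2 change of -2.77 ± 0.35, and 2 fell without AdCre sphere replicate 2; the list's median of -0.34 was 0.10 after quantile normalization. Notch pathway genes fell for 9 of 18, led by Lfng at -2.69 ± 0.23, and 3 fell without AdCre sphere replicate 1. Among Ink4a-Arf and senescence genes 5 of 8 fell, with the cell cycle inhibitors Cdkn2b at -2.36 ± 0.23 and Cdkn1b at -1.83 ± 0.28.

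The count rested on both spheres, at 3950 without AdCre sphere replicate 1 and 4479 without AdCre sphere replicate 2, and 10249 transcript clusters had an unadjusted p under 0.05. Groups did not overlap for 54.1% of transcript clusters, where chance gives 13.3%, and sphere values were wider spread, with interquartile ranges of 3.65 to 3.78 against 2.80 to 3.07 in tumours. Quantile normalization gave 5474 changed transcript clusters, 2604 higher and 2870 lower, and 72.5% of changed named genes were then lower, against 89.9% as deposited.

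The third comparison, PNET (n = 3) against AdCre spheres (n = 2), asks the same of the embryonal tumour. Sox2 was lower in PNET by a log2 change of -6.81 ± 0.29 (adjusted p = 4.935e-06), at 4.45 ± 0.50 (SD, n = 3) against 11.26 ± 0.10 (SD, n = 2) in spheres. Among photoreceptor and pineal genes, Crx was higher by 6.04 ± 0.45 (adjusted p = 4.688e-05) and Otx2 by 5.58 ± 0.44 (adjusted p = 5.873e-05), from 5.96 ± 1.24 in spheres. The astrocyte enzyme Aldh1l1 was lower by a log2 change of -6.09 ± 0.42 (adjusted p = 3.526e-05). With an estimated correlation camera called 0 lists in this comparison as well, with adjusted p = 0.139 for the photoreceptor and pineal genes and 0.283 for the astrocyte genes. In all, 8590 transcript clusters changed, 2564 higher and 6026 lower in PNET, or 804 and 4769 named genes, and the median over named genes was -0.36 as deposited and -0.18 after quantile normalization.

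Tc2n (7.10 ± 0.76), Impg2 (6.61 ± 0.31), Tmem215 (6.28 ± 0.32), Tph1 (6.23 ± 0.46), Pde6c (6.02 ± 0.41), Neurod1 (5.77 ± 0.39), Rbp3 (5.67 ± 0.24), Neurod4 (5.53 ± 0.69), Ctss (5.26 ± 0.81) and Cyyr1 (5.15 ± 0.41) were the other largest rises. Large falls besides Sox2 and Aldh1l1 were the neuronal and glial membrane protein Gpm6a (-6.22 ± 0.60), Hepacam (-5.88 ± 0.30) and Mlc1 (-5.73 ± 0.39), which form an astrocyte membrane complex, angiotensinogen, Agt (-5.76 ± 0.73), and the neural transcription factor Pou3f4 (-5.65 ± 0.65). Plppr5 (-5.55 ± 0.68), the noncoding RNA Pantr1 (-5.55 ± 0.22), the axonal transport gene Fez1 (-5.40 ± 0.32) and the glucose transporter Slc2a3 (-5.32 ± 0.39) followed. For 10 of the 24 largest changes, among them Tc2n (2.41 in spheres) and Pou3f4 (3.15 in PNET), the dimmer group lay below the lower quartile of its arrays, where background limits the size. Of the 24 only Nap1l5 (-5.48 ± 1.32) failed to pass with a sample left out, at adjusted p = 0.0556 without AdCre sphere replicate 1. Rb1 was 1.04 ± 0.26 higher in PNET (adjusted p = 0.0130), and did not pass without AdCre sphere replicate 2 (adjusted p = 0.0899) or with the AdGFP sphere added (adjusted p = 0.561).

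Photoreceptor and pineal genes rose for 12 of 25 members and fell for 1, also adjusted over the list alone, with a median of 1.24, or 1.60 relative to all named genes. The fall was Rcvrn (-0.50), a photoreceptor calcium sensor, which did not pass without AdCre sphere replicate 2 (adjusted p = 0.146). The list's adjusted p was 3.452e-13, and adjusted p = 0.139 with an estimated correlation, and its median was 0.64 without PNET replicate 2. Microglia and macrophage genes rose for 10 of 26, also adjusted over the list alone, with C1qb at 3.66 ± 0.62 and a relative median of 1.27 (adjusted p = 6.894e-09; adjusted p = 0.325 with an estimated correlation). Their number was 4 without PNET replicate 2, PNET replicate 3 or AdCre sphere replicate 2, and 3 without AdCre sphere replicate 1, and the median of 0.91 was 0.60 without PNET replicate 3. E2F and S-phase genes rose for 7 of 36 and fell for 1 (4 and 0 adjusted over the list alone), with a relative median of 0.72. Thymidylate synthase, Tyms, rose by 1.42 ± 0.25 and the replication licensing factor Cdc6 by 1.32 ± 0.23. Camera gave that list adjusted p = 1.46e-08, and adjusted p = 0.283 with an estimated correlation, and 3 and 4 rose without AdCre sphere replicate 1 and 2, with a median of 0.21 in place of 0.36 without AdCre sphere replicate 1.

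Endothelial genes had 5 rises and 4 falls in 24, also adjusted over the list alone, with Emcn at 2.21 ± 0.40 and Cdh5 at 1.73 ± 0.33, and a relative median of 0.77 (adjusted p = 0.000222; adjusted p = 0.283 with an estimated correlation). The endothelial median was 0.41, and 0.24 without PNET replicate 2. Pericyte and smooth muscle genes had 6 rises and 2 falls in 16 (6 and 3 adjusted over the list alone), led by vitronectin, Vtn, at 4.77 ± 0.86, with a relative median of 0.66, adjusted p = 0.000499 and adjusted p = 0.283 with an estimated correlation. Without AdCre sphere replicate 1, 3 pericyte genes rose, and without AdCre sphere replicate 2, 1. Fibroblast and matrix genes had 4 rises and 1 fall in 27 (2 and 1 adjusted over the list alone), with Bgn at 3.59 ± 0.38, thrombospondin Thbs1 at 3.41 ± 0.77 and Timp1 at -2.97 ± 0.53. Their relative median was 1.10, with adjusted p = 1.419e-05 and adjusted p = 0.283 with an estimated correlation, and 2 rose without PNET replicate 1 or AdCre sphere replicate 2. The choroid plexus and ependyma genes had 4 rises and 1 fall in 16 (3 and 1 adjusted over the list alone), with Calml4 at 4.15 ± 0.65 and the cilium gene Rsph1 at -1.36. Their adjusted p was 0.000398, with adjusted p = 0.139 with an estimated correlation and adjusted p = 0.0534 after quantile normalization.

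Astrocyte genes fell for 20 of 25 (21 adjusted over the list alone), with a median of -3.39, or -3.03 relative to all named genes. Acsbg1 changed by -4.81 ± 0.46 and Fgfr3 by -4.63 ± 0.23, and the list's adjusted p was 2.649e-07, with adjusted p = 0.283 with an estimated correlation. Oligodendrocyte precursor genes fell for 16 of 23 (17 adjusted over the list alone), with a relative median of -1.87, Olig1 at -4.22 ± 0.28 and Olig2 at -3.85 ± 0.21. Their adjusted p was 0.000168, and adjusted p = 0.283 with an estimated correlation. Neural stem and progenitor genes fell for 16 of 24 and rose for 1, also adjusted over the list alone, with a relative median of -1.65, Egfr at -5.03 ± 0.37, Nr2e1 at -3.91 ± 0.39 and Emx2 at -3.68 ± 0.27. This list's adjusted p was 0.00285, and adjusted p = 0.283 with an estimated correlation, or 0.0691 without the dimmer transcript clusters. Cholesterol synthesis genes fell for 16 of 18 (18 adjusted over the list alone), with a relative median of -1.63, Hmgcs1 at -3.69 ± 0.35 and Cyp51 at -3.07 ± 0.39. Camera gave adjusted p = 2.085e-06, and adjusted p = 0.288 with an estimated correlation. Hypoxia genes fell for 15 of 22 and rose for 1 (16 and 1 adjusted over the list alone), with a relative median of -1.59, the kinase Pdk1 at -3.63 ± 0.50, adjusted p = 0.00420 and adjusted p = 0.486 with an estimated correlation.

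Of the 14807 named genes, 4769 fell in PNET, and the lists that follow were not called. Mature neuron genes went both ways, with 7 rises and 6 falls in 24 (list adjusted p = 0.0875). Snap25 (3.93 ± 0.68), Slc17a7 (3.51 ± 0.57) and Syp (3.04 ± 0.39) rose, and Stmn3 (-3.08 ± 0.61) and Syn2 (-2.38 ± 0.46) fell; 4 rose without either AdCre sphere. Receptor tyrosine kinase and ligand genes fell for 14 of 25 and rose for 1, with Ntrk2 at -5.30 ± 0.75 (camera adjusted p = 0.231). p53 target genes fell for 12 of 33 and rose for 1, with Abhd4 at -3.81 ± 0.25, and 6 fell without AdCre sphere replicate 1. Their median relative to all named genes was -0.11 (camera adjusted p = 0.800). Immediate early and stress genes fell for 14 of 24, with Nr4a1 at -2.23 ± 0.35 (list adjusted p = 0.0902), and 7 fell without AdCre sphere replicate 1. Neuronal lineage progenitor genes fell for 9 of 29, among them the GABA enzyme Gad1 at -4.22 ± 0.48, while Neurod1 and Neurod4 were the 2 rises. That list's relative median was -0.20 (camera adjusted p = 0.800).

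The count was 5233 without AdCre sphere replicate 1, 10726 transcript clusters had an unadjusted p under 0.05, and 61.5% had groups that did not overlap, where chance gives 20%. Quantile normalization gave 6700 changed transcript clusters, 3267 higher and 3433 lower, and 65.4% of changed named genes were then lower, against 85.6% as deposited.

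Both tumour types were compared with the same 2 AdCre spheres. Of the named genes, 190 were higher in both and 3149 lower in both, where independent lists would share 25.6 and 1349. Opposite calls were made for 68 genes, fewer than independent lists would give. Of these, 42, against 152 expected, were higher in oligo-astrocytoma and lower in PNET, among them Pdgfra (3.74 and -2.64), Sox10 (2.62 and -1.24), Bcas1 (3.14 and -2.03) and Sox6 (1.39 and -4.13). The other 26, against 227 expected, went the opposite way, among them Cdon (-0.92 and 1.37). Over named genes the changes correlated at 0.603, below the 0.613 to 0.651 of simulated unchanged groups that share 2 control samples, and over all transcript clusters at 0.737, above the simulated 0.614 to 0.646. In unchanged groups the group sizes set this correlation, and it carries no scale. It therefore cannot say whether more or less is shared than shared controls give. The covariance of the changes was 0.473 over named genes and 0.732 over all transcript clusters, against simulated means of 0.0627 and 0.0695. The directions matched for 79.5% of named genes and 81.6% of transcript clusters, against a simulated mean of 71.8% for both.

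**Figure D3:**
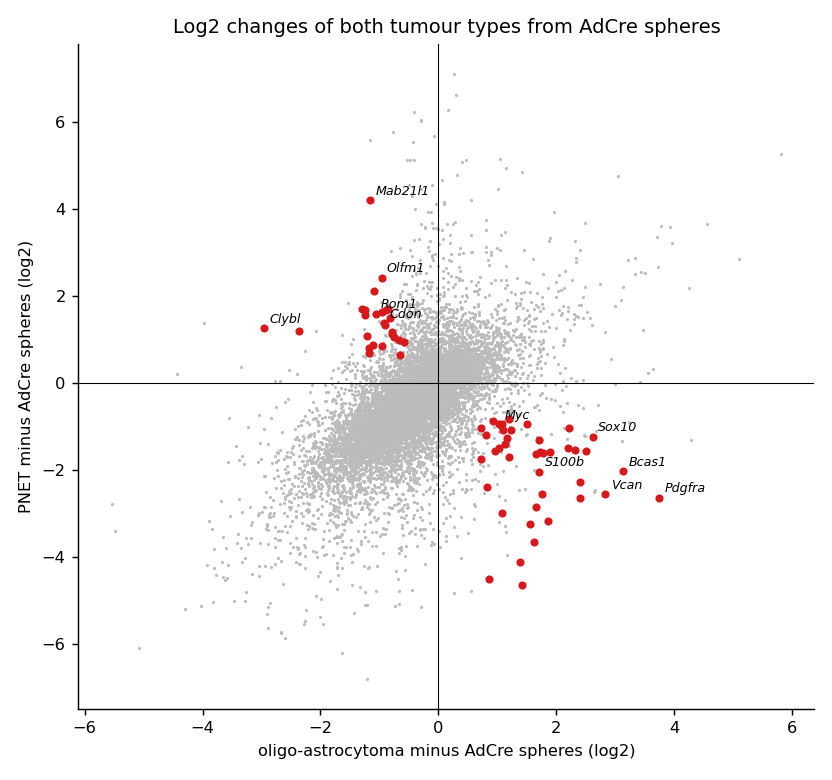
Log2 change of each named gene from AdCre spheres in oligo-astrocytoma (horizontal axis) and PNET (vertical axis), 1 point per gene. Red points are the 68 genes called in opposite directions, 42 at the lower right and 26 at the upper left, with Pdgfra at 3.74 and -2.64.

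The fourth comparison, AdCre spheres (n = 2) against the AdGFP sphere (n = 1), addresses the effect of AdCre on the cultures. The lone AdGFP sample was assumed to vary like the other groups. p53 target genes were lower as a group, with a median of -0.70 over 33 members, 1 fall (9 adjusted over the list alone), adjusted p = 4.717e-32 and adjusted p = 0.000950 with an estimated correlation. The fall was Dglucy, an enzyme of D-glutamate, at -2.90 ± 0.29 (adjusted p = 0.0414), from 8.86 in the AdGFP sphere to 5.96 ± 0.17 (SD, n = 2). The p53-induced nuclease Aen was at -1.76 ± 0.29 and Rb1 at -1.99 ± 0.35, neither of which passed (adjusted p = 0.247 for both). Cdkn1a (-2.03 ± 0.69) and Ccng1 (-1.91 ± 0.39), singled out after their values were seen, did not pass either.

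Mesenchymal glioma genes (median 0.62, adjusted p = 0.00535), interferon and MHC class I genes (0.90, 0.0120) and hypoxia genes (0.35, 0.0145) were higher in AdCre spheres as groups, each with adjusted p = 0.986 with an estimated correlation. So were forebrain patterning genes (0.34, adjusted p = 0.00587; adjusted p = 0.275 with an estimated correlation). No member of these 4 lists passed in limma over all genes. Among their members, Ifit1 was at 3.73 ± 1.87, S100a6 at 1.94 ± 0.79, Emx2 at 0.78 ± 0.36 and carbonic anhydrase Car12 at 1.34 ± 0.27, the latter passing adjusted over the list alone. The hypoxia call was lost without AdCre sphere replicate 2 (adjusted p = 0.484), and the forebrain and interferon calls without AdCre sphere replicate 1 (adjusted p = 0.0618 for both). Without the dimmer transcript clusters the hypoxia and forebrain calls were lost (adjusted p = 0.0748 for both). Cdkn2a, which encodes the Arf and p16 tumour suppressors, was at 1.69 ± 0.36 (adjusted p = 0.375).

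In this comparison 4 transcript clusters changed, 1 higher and 3 lower, of which only Dglucy has a gene name, and 1152 had an unadjusted p under 0.05. None passed in limma without AdCre sphere replicate 1 or without AdCre sphere replicate 2, where Dglucy stood at an adjusted p of up to 0.123.

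The fifth comparison, the AdCre-induced oligo-astrocytoma (n = 1) against the grafted oligo-astrocytomas (n = 3), addresses how the origin of the tumour relates to its expression. The lone sample was assumed to vary like the other groups. Ifitm3, an interferon-induced antiviral membrane protein whose gene lies in a run of raised neighbours on chromosome 7, was 5.04 ± 0.36 higher in the AdCre-induced tumour (adjusted p = 0.00273), at 12.21 against 7.17 ± 0.30 (SD, n = 3). Of the 20 interferon and MHC class I genes 3 passed, and the call of that list was lost with an estimated correlation (adjusted p = 0.839). The guanylate-binding protein Gbp5 was 3.60 ± 0.34 higher (adjusted p = 0.00694). Impact, an imprinted regulator of translation, was lower by a log2 change of -3.68 ± 0.34 (adjusted p = 0.00686), at 5.10 against 8.78 ± 0.23. Of 70 changed transcript clusters, 67 were higher and 3 lower, or 59 and 1 named genes, and with only these 4 samples in the limma fit 0 passed.

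Several genes with the smallest p-values lie near the end of chromosome 7 in the GRCm38.p6 assembly. These were the lipase Pnpla2 (3.46 ± 0.24), the phospholipid enzyme Ptdss2 (3.51 ± 0.25), the ribonuclease inhibitor Rnh1 (3.29 ± 0.26), the transfer RNA synthetase Cars (3.23 ± 0.27) and the adaptor subunit Ap2a2 (3.09 ± 0.26). Ano1, a chloride channel, at 2.37 ± 0.26 and Dhcr7, the last enzyme of cholesterol synthesis, at 1.98 ± 0.25 also rose. Without grafted replicate 5, adjusted p was 0.0511 for Ano1, 0.0788 for Dhcr7, 0.0545 for Tspan4 (4.12 ± 0.49), 0.0763 for Gbp2 (3.73 ± 0.45) and 0.0503 for the nucleic acid sensor Zbp1 (3.64 ± 0.39). Ccnd1, the G1 cyclin, read 12.81 against 9.43 and did not pass (3.39 ± 0.92; adjusted p = 0.320).

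Interferon and MHC class I genes rose for 3 of 20 members (18 adjusted over the list alone), with a median of 2.82, adjusted p = 5.949e-26 and adjusted p = 0.839 with an estimated correlation. The 3 were Gbp2, the immunoproteasome subunit Psmb8 at 3.04 ± 0.40 and the peptide transporter Tap2 at 1.92 ± 0.29, and 0 rose without grafted replicate 5 or grafted replicate 6. Microglia and macrophage genes had 0 of 26 members past the limma threshold (19 higher adjusted over the list alone) and a median of 1.36, with adjusted p = 2.291e-12 and adjusted p = 0.959 with an estimated correlation. H2-Ab1 and H2-Aa, which present antigen, were at 3.42 ± 1.12 and 3.41 ± 1.17. The cholesterol synthesis genes (median 0.26, 1 rise, adjusted p = 0.0406) and mesenchymal glioma genes (0.66, 0 rises, adjusted p = 0.0465) were called higher, each with adjusted p = 0.959 with an estimated correlation. Both calls were lost without grafted replicate 5 (adjusted p = 0.0520 and 0.111), and the mesenchymal call also without grafted replicate 6 (0.0978). The mature oligodendrocyte genes had a median of -0.47 (adjusted p = 0.0553; adjusted p = 0.959 with an estimated correlation), which rests on grafted replicate 4, whose list mean was 8.90 against 7.56 and 6.76 in the other grafts and 7.26 in the AdCre-induced tumour. Adjusted p was 0.779 without grafted replicate 4, 0.0225 without grafted replicate 5 and 5.963e-07 without grafted replicate 6.

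The count was 28 without grafted replicate 5 and 32 without grafted replicate 6, and 1755 transcript clusters had an unadjusted p under 0.05.

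Expression was also set in gene order along the 20 chromosomes, for 10812 genes of GRCm38.p6. In the AdCre-induced oligo-astrocytoma a run of 67 neighbouring genes at the end of chromosome 7, from Olfr532 to Mrgprf, had a median difference of 2.04 from the median of the other oligo-astrocytomas. Of these genes 63 had a difference above 0, and the run held Ifitm3, Irf7, Igf2 and Ccnd1. It included 32 of the 59 named genes higher in the fifth comparison. In grafted replicate 6, 64 genes at the start of chromosome 12, from Rab10os to Dld, had a median difference of 0.95, while the median of the whole of chromosome 12 was -0.40, and 0.38 in the AdCre-induced tumour. Runs numbered 23, 4 and 6 in PNET replicates 1, 2 and 3, 15 in the AdCre-induced tumour, 3, 2 and 8 in grafted replicates 4, 5 and 6, and 0 in each sphere, with at most 1 per sample in any shuffle of gene order. The AdCre-induced tumour had 6 other runs on chromosome 7, all lower, with medians of -0.52 to -0.58. In PNET replicate 3, 21 genes of a protocadherin cluster on chromosome 18, from Pcdhb2 to Taf7, had a median of -1.65 and a running median 1.60 from 0, the largest after the run at the end of chromosome 7.

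**Figure D4:**
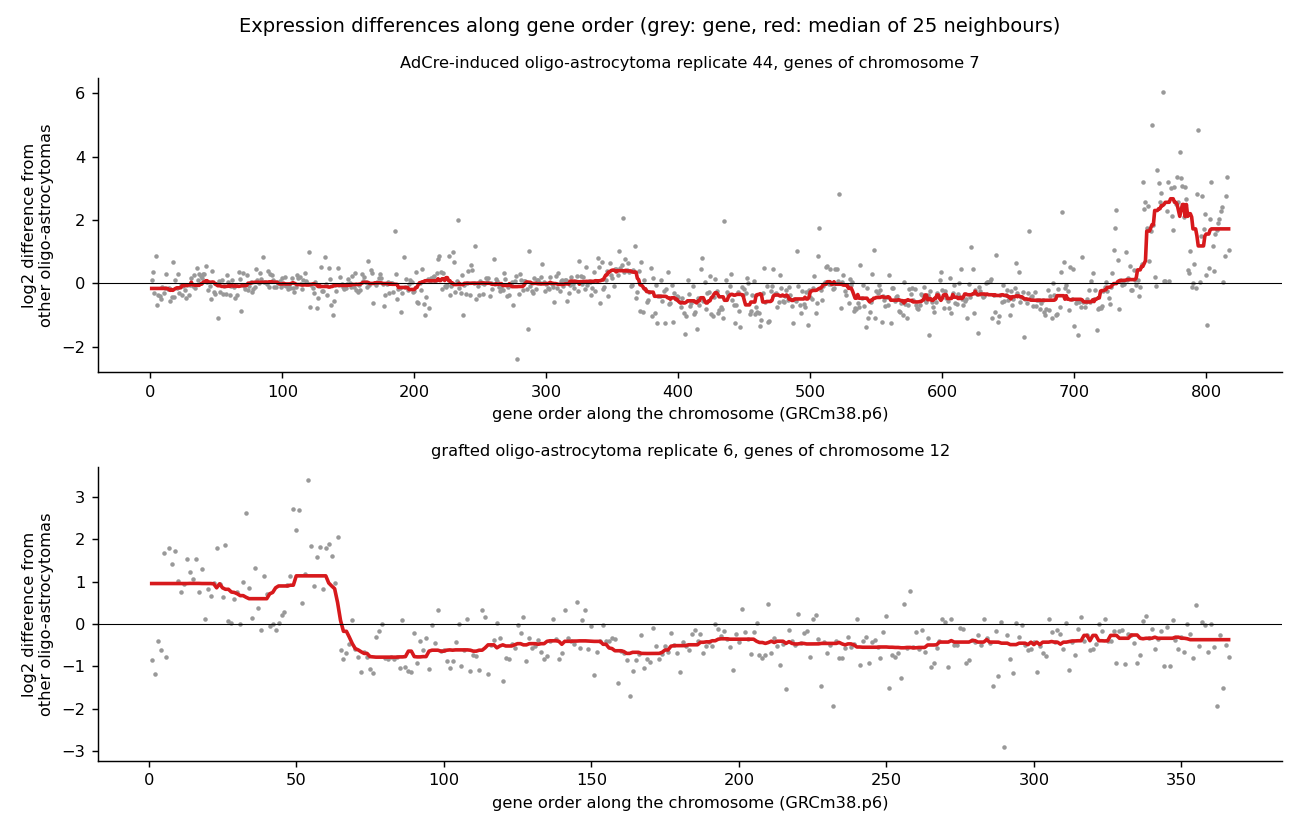
Log2 difference of single genes (grey points) and the median of 25 neighbours (red line) from the other oligo-astrocytomas, in gene order of GRCm38.p6 along chromosome 7 of the AdCre-induced tumour and chromosome 12 of grafted replicate 6. The red line reaches 2.67 at the end of chromosome 7 and 1.13 near the start of chromosome 12.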

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

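Of the tests in this part, those on shuffled gene order, on interferon genes and gene families within the run, and on interferon genes outside it were chosen only after the result was seen.

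Relative to the same AdCre spheres, 42 named genes were higher in oligo-astrocytoma and lower in PNET, and 26 were lower in oligo-astrocytoma and higher in PNET. The difference between the tumour types passed for each of these genes, as opposite calls against the same spheres fix beforehand, and independent lists would give 152 and 227 such genes. Of the 42, the 7 with the largest differences were Pdgfra at 3.74 in oligo-astrocytoma and -2.64 in PNET, Vxn at 1.43 and -4.66, Sox6 at 1.39 and -4.13, Vcan at 2.83 and -2.57, Adgrl3 at 0.87 and -4.51, Ncam2 at 1.62 and -3.66, and Bcas1 at 3.14 and -2.03. Myc was at 1.04 and -0.96, and did not pass without AdCre sphere replicate 2 in the first (adjusted p = 0.121) or without AdCre sphere replicate 1 in the second (adjusted p = 0.156). In the other direction, Mab21l1 was at -1.16 and 4.20, Olfm1 at -0.96 and 2.42, Rom1, a photoreceptor disc protein, at -1.06 and 1.59, and Cdon at -0.92 and 1.37.

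Among 320 named genes and 30 list means in the 4 oligo-astrocytomas, 24 genes had 1 sample apart from the other 3. For these the gap to the nearest, as a share of the whole range, lay beyond the critical value of Dixon's test. Chance gives about 1 in 20, and 24 of 350 lies near that share. A share of the range carries no scale, so small gaps count too, as for Liph (2.85 against 2.62 to 2.64) and Insig1 (9.07 against 8.50 to 8.53). The AdCre-induced tumour stood apart for 17 of the 24, and the genes named for the fifth comparison had been picked for such a gap. It was highest for Ano1 (a gap of 0.946 of the range), Pnpla2 (0.922), Ptdss2 (0.921), Cars (0.916), Ap2a2 (0.883), Rnh1 (0.877) and Dhcr7 (0.841), all in a run of neighbouring genes on chromosome 7. For the interferon-induced genes Zbp1 (0.900), Gbp5 (0.892), Ifitm3 (0.890) and Gbp2 (0.887) it was also highest, as for Insig1 (0.953), Il6 (0.912), Glb1 (0.845) and Gngt1 (0.838). It was lowest for Impact (0.882), at 5.10 against 8.53 to 8.99, and for Cd79b (0.890). Grafted replicate 6 was highest for Clic6 (0.963), Zic1 (0.935) and Kcnip1 (0.846), and lowest for Ccng1 (0.903) and Nap1l5 (0.857), which read 3.87 against 8.47 to 9.24. Grafted replicate 5 was highest for Liph (0.899) and Nrarp (0.898).

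In the AdCre-induced tumour, neighbouring genes at the end of chromosome 7 reached a running median of 2.67, while the highest in any of 100 shuffles of gene order was 0.539, which argues against noise of a single array; with shorter medians at chromosome ends, an alternative added after the data were seen, the values were 2.78 and 2.47. Without interferon genes and with 1 gene for each name up to its first digit, the 61 remaining genes of the run had a median of 2.10. Of the 67 genes of the run, 47 had a difference above 1, so leaving out so few could not have lowered the median far. Co-regulated families as the source are therefore not tested by this. Extra copies of the segment are a candidate explanation, since of 11 dim genes between its ends that the scan had left out, 6 (54.5%) lay above all 3 grafts, where chance gives 25%, with a median difference of 0.37 and a range of -0.16 to 0.82. That test passed its bound of 50% by 1 gene, and DNA was not analysed here, so a change in copy number remains a hypothesis. The 19 interferon and MHC class I genes outside chromosome 7 had a median of 2.61 and each lay above every graft, so their own position in the run is not what raised them. The run holds Irf7, a regulator of interferon genes, at 6.05, so an indirect effect of the run stays open, as does the origin of the tumour, a biological difference that was not tested.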

How the results depend on the processing

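Of the alternatives, 4 were added after seeing the data: the rule at chromosome ends, with values of 2.78 and 2.47 in place of 2.67 and 0.539, PNET against AdCre spheres in the samples of the block below without the number, with 7921, and 2 for the interferon list. Named genes kept their side of the threshold in 6471 of their repeats, lost their call in 780, gained one in 19 and reversed in 0. For genes and lists, a change of sign where neither fit passed counted as the same, so reversals need a pass. List tests stayed the same in 1177, were weaker in 55, stronger in 47 and reversed in 3, and counts stayed within 1.5 times in 90 and moved in 23. PNET against oligo-astrocytoma gave 1182 changed transcript clusters with the AdCre-induced tumour alone on the oligo-astrocytoma side, where 1 sample leaves less power. PNET against AdCre spheres gave 4295 with a block for the sample number, against 7921 in the same samples without it. The block leaves 1 residual degree of freedom and takes PNET replicate 3, the only sample with that number, out of the contrast (7101 without that replicate). The labels do not say whether equal numbers mark the same animal. Deviations from the group mean correlated at -0.0329 and -0.0579 between same numbers. With 2 spheres these deviations mirror each other, so the values say little about pairing. AdCre against AdGFP spheres gave 0 with quantile normalization, with trended and robust moderation, without moderation and with only the compared groups in the limma fit, and 2 without transcript clusters dimmer than the median, against 4 as reported. The AdCre-induced against the grafted oligo-astrocytomas gave 7 without moderation and 0 with only the compared groups, against 70. Leaving out single replicates gave 1772 to 2781 for PNET against oligo-astrocytoma, 3950 to 7234 and 5233 to 8088 for oligo-astrocytoma and PNET against AdCre spheres, 0 to 0 for the spheres and 28 to 75 within oligo-astrocytomas. The lowest counts came without PNET replicate 3 (1772), AdCre sphere replicate 1 (3950 and 5233) and grafted replicate 5 (28), and 4479 and 32 came without AdCre sphere replicate 2 and grafted replicate 6.

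With an estimated correlation camera called 0 lists in place of 11, 10 and 12 in the main comparisons. It called 1 in place of 5 between spheres and 0 in place of 4 within oligo-astrocytomas. In PNET against oligo-astrocytoma, calls were lost even where the estimate lay below the preset 0.01. These were the receptor tyrosine kinase (0.00564) and the choroid plexus and ependyma genes (0.00840). A larger correlation alone therefore does not account for the loss, and the cause was not tested. Adjusted p-values given here with an estimated correlation thus do not measure the effect of correlation between genes alone. Leaving out replicates gave 11 to 12, 10 to 12, 12 to 15, 5 to 9 and 5 to 5 lists, with 9 between spheres without AdCre sphere replicate 2. The fry test asks whether a list changed at all. For the 11 lists called in PNET against oligo-astrocytoma, its false discovery rate was 0.202 for mitosis and 0.269 for microglia and macrophage genes. It was at most 0.0255 for the others, and 0.0150 and 0.00961 for the uncalled neural stem and progenitor and Wnt lists. Reversed were the interferon and MHC class I genes in PNET against the AdCre-induced tumour alone (-2.02, adjusted p = 1.704e-07), the E2F and S-phase genes between spheres without AdCre sphere replicate 2 (-0.0445; 0.285 without AdCre sphere replicate 1) and the mitosis genes within oligo-astrocytomas without grafted replicate 5 (0.319; -0.135 without grafted replicate 6); the cause was not tested. The interferon list was called in PNET without the AdCre-induced tumour (adjusted p = 0.000323), but not with an estimated correlation there (0.638) or against that tumour alone (0.541). After quantile normalization the median of uncalled lists changed sign for cholesterol synthesis, hypoxia and Sonic hedgehog genes in PNET against oligo-astrocytoma, E2F and MYC genes in oligo-astrocytoma against spheres, and interferon, mature neuron and mitosis genes in PNET against spheres. It also did so for mature neuron genes between spheres and for E2F, mitosis, MYC and photoreceptor genes within oligo-astrocytomas. A log transformation was not run as an alternative, since the values are log2. Background signal on the arrays limits dim transcript clusters, and the smallest detectable change is set by the number of arrays.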

Other observations

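Of the tests in this part, those on retinal and pineal markers and on shifted chromosomes were chosen only after the result was seen.

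Hindbrain and cerebellar genes had 3 rises and 1 fall in 19 members between PNET and oligo-astrocytoma (list adjusted p = 0.462). Cbln1, a synapse organizer of cerebellar granule cells, was 2.12 higher, the cerebellar factor Zic2 1.91 and Barhl2 1.23, while Meis1 was at -1.67 and did not pass without grafted replicate 5 (adjusted p = 0.0880). Wnt response genes fell for 3 of 13 in that comparison, among them Tcf7l2, a transcription factor of the pathway, by a log2 change of -2.05 ± 0.27. They fell for 6 of 13 in PNET against AdCre spheres (3 without PNET replicate 1, PNET replicate 3 or AdCre sphere replicate 2, and 2 without AdCre sphere replicate 1). Camera called the Wnt list in neither (adjusted p = 0.203 and 0.444). Lymphocyte genes (19 measured) and red blood cell genes (6 measured) had at most 2 changes in any comparison. In limma none of 19 lymphocyte genes passed between PNET and oligo-astrocytoma (list adjusted p = 0.264).

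Changes of retinal and pineal genes between PNET and oligo-astrocytoma ranged from -0.06 to 6.65. Tph1 rose by 6.65 (3.61 to 10.26), Chrna3 by 5.67, the cone transducin subunit Gnb3 by 4.69, and the rod and cone disc genes Abca4, Prph2 and Rom1 by 3.61, 2.90 and 2.66. Sag, the rod arrestin, rose by 2.30 (4.82 to 7.12) and the rod transducin subunit Gnat1 by 1.66 (3.70 to 5.37; adjusted p = 0.0200). Recoverin, Rcvrn (-0.06), the rod genes Guca1b (0.09), Gngt1 (0.10) and Nrl (0.29), and Aanat (0.36), the enzyme that times melatonin synthesis, did not pass (adjusted p = 0.860, 0.774, 0.802, 0.429 and 0.261). Rcvrn read 6.28 and 6.34, Gngt1 1.94 and 1.84, and Aanat 4.69 and 4.34 in PNET and oligo-astrocytoma.

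A source of the photoreceptor and pineal genes could be retinal tissue or normal pineal gland within the PNET samples, which would bring the abundant genes of that tissue. Of the list, Otx2, Tph1, Crx, Chrna3 and Gnat2 were among the 12 largest rises, by 5.62 to 6.74. All 16 measured rod genes had a median of 1.18 with an SD of 1.10 and 0 reached 5.62, and all 14 measured pineal genes, which include Tph1 and Chrna3, had a median of 1.67 with an SD of 2.13, but those 5 were picked for their size, so this excludes neither tissue. Of the markers, 10 rod and 9 pineal genes also stand in the photoreceptor and pineal list; the other 6 had a median of 1.20 with 2 higher, and the other 5 a median of 1.69 with 2 higher, so neither source is excluded or established. Expression of these genes by the tumour cells themselves was not tested, and stays open.

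Falls outnumbered rises in both tumour types relative to AdCre spheres, whose arrays have a wider spread of values. Quantile normalization evens out the arrays over all transcript clusters and not within a class, so shares within a class cannot test that spread as the source. Of the named genes called after it, 72.5% were lower in oligo-astrocytoma and 65.4% in PNET. These shares are over fewer genes, as called falls went from 4189 to 2254 and from 4769 to 2705. Among the 5810 brightest transcript clusters, the share of calls that were lower went from 84.7% to 44.9% in oligo-astrocytoma and from 86.4% to 51.0% in PNET. Among the 5810 dimmest, that share went the other way, from 48.8% to 64.6% and from 49.4% to 63.7%. Over all transcript clusters the share of rises went from 30.7% to 47.6% and from 29.8% to 48.8%, a balance that quantile normalization brings about, so the spread may account for the excess there. Of called transcript clusters with no gene listed, 68.2% and 63.5% were higher as deposited and 78.9% and 76.0% after quantile normalization, which mirrors the falls of named genes, and a difference between tissue and cultured cells, which the design names, stays open as untested.

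Part of the excess of genes shared by both tumour types may come from the shared controls, since both comparisons used the same 2 AdCre spheres. The overlap with a different AdCre sphere in each comparison was not computed. With the AdGFP sphere added to the AdCre spheres, 8736 and 9354 transcript clusters were called. Of all splits of the 7 tumours into 3 and 4, only 1 of 35, the real one, gave as many changed transcript clusters. It gave 2960, against at most 5 in any other. Every other split mixes the tumour types, which widens the spread within groups, so low counts there were likely beforehand. The test therefore does not exclude chance, and it cannot separate tumour type from derivation.

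Chromosome medians differed between tumours of the same type. The median of a chromosome lay beyond 0.15 from the other samples of the same type in 48 of 140 pairs of tumour and chromosome, in 0 of 60 pairs in spheres and in 0 pairs in each of 100 shuffles of gene order, which argues against an order of genes without effect. Shifted chromosomes numbered 10, 9 and 6 in PNET replicates 1, 2 and 3, 4 in the AdCre-induced oligo-astrocytoma, and 7, 4 and 8 in grafted replicates 4, 5 and 6. Chromosome 17 was at -0.41 in PNET replicate 3 and 0.39 in PNET replicate 1, and chromosome 12 at -0.40 in grafted replicate 6 and 0.38 in the AdCre-induced tumour. Each value is a difference from 2 or 3 other samples, so a change in 1 tumour also moves the values of the others, and the 48 do not say which tumour changed. Changes in chromosome number are a possible explanation that was not tested against DNA.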
